A study of Mus musculus with 12 samples.

How the data were processed

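Liver RNA of male ICR mice was measured on 12 Agilent 1-colour (Cy3) mouse arrays. Per the labels' protocols, the mice were 5 weeks old and were adapted for 1 week, and diethylnitrosamine (DEN, a liver carcinogen that alkylates DNA) was given in the drinking water at 80 mg/L, about 400 µg per day. All-trans retinoic acid (ATRA, the active form of vitamin A) was given in the drinking water at 30 mg/L, about 150 µg per day. Small interfering RNA (siRNA) against G0s2, or a control siRNA, was injected intravenously at 1.6 nmol with a lipid carrier. The protocol places the siRNA on the day before DEN, whereas the labels of the siRNA arrays name only the siRNA, so whether those mice drank DEN is not stated. The labels do not say whether an array holds RNA of 1 animal or of a pool. RNA was isolated with TRIzol and labelled with a low-input Quick Amp kit, per the labels' protocols.

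The deposited array files hold the processed spot intensities of Agilent Feature Extraction, background-subtracted, detrended and with surrogate values for dim spots, per the file headers. The file headers name version 10.7.1.1 of that program, and the submitters' processing notes name version 9.5.1.1. The deposited series table holds linear intensities that the authors had normalized. Its sorted values were equal within each day to within 0.083% at day 2 and 0.053% at day 7, which shows quantile normalization done separately for each day, so it was used only for comparisons within a day and only as an alternative. Each column of that table correlated across probes with its own array at r above 0.999.

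The 12 arrays form 6 treatments at 2 times, day 2 and day 7, with 1 array per group and therefore no replicates within any group. They lie on 4 slides, scanned on 3 days. Slide 1 holds vehicle, ATRA, DEN and ATRA+DEN of day 2, slide 2 both siRNA arrays of day 2, slide 3 vehicle and DEN of day 7, and slide 4 the other 4 arrays of day 7. For 3 day-7 arrays the treatment characteristic disagrees with the title and the source name, which match each other. Titles were used. By the characteristic, the array titled DEN would be ATRA, the array titled ATRA+DEN would be DEN, and the array titled ATRA would be ATRA+DEN.

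Of 62976 spots per array, 59305 were not controls, and they made up 55681 probes after spots of 1 probe were averaged on the log2 scale. Between 41.0% and 50.7% of probes were well above background on an array, and no probe was saturated. Their number, 1 array per group, limits the precision. The processed intensities were log2 transformed and each array's 75th percentile was subtracted, so a level of 0 is that percentile. Probes were named through the accession, symbol or synonym in the reference table, which covered 27235, 3581 and 565 probes, and 24300 kept the name in the array file. A gene was represented by its probe with the highest mean level, and was tested if that probe was well above background on at least 2 of the 12 arrays, which left 21186 of 34741 genes.

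Genes were tested with limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The DEN effect was the mean over 4 pairs of arrays that differ in DEN, with the pair as a block and the siRNA pairs sharing the estimate of spread. The G0s2 siRNA effect was the mean over 2 pairs in the same fit. The ATRA effect was the mean over 4 pairs, among the 8 arrays without siRNA. The DEN by ATRA interaction had slide as a block, and the day comparison was made over 6 pairs with treatment as a block. Differences between single arrays were given without a test, as counts of genes at least 2-fold apart. Gene lists, 33 in number, were tested with camera at a preset correlation of 0.01, adjusted over 165 tests, and again with an estimated correlation. They were also tested with fry, which tests the members of a list without comparing them with other genes, adjusted in the same way. For single arrays, the median of a list was placed among 10000 random lists matched on level.

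Named genes followed a rule. G0s2, Cyp26a1, Cdkn1a and Mdm2 were given in every array. For each comparison, the 10 largest rises and 10 largest falls that passed with the same sign in every pair were named, and where fewer than 5 passed in a direction, the largest with the same sign in every pair and above background on every array filled up to 5. Up to 4 passing members of a list, or up to 2 if none passed, and the 5 largest rises and falls of single-array differences with the same sign in the matched difference were also eligible. Predicted genes and clone names were counted and not named, and 2 genes that met the rule are not reported here. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

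The fits were tested on simulated data with 50 changed genes per fold. At a 4-fold change, 78% were recovered for DEN, 78% for ATRA, 60% for G0s2 siRNA and 94% for day. At a 2-fold change the shares were 36%, 30%, 8% and 74%. The simulated noise of every comparison was drawn from the spread of the DEN fit, whose pairs lie within slides, and held no slide effect. The day-7 ATRA pairs and all day pairs span slides, so the shares for ATRA and day may be too high. The interaction fit recovered 0 of 50 genes even at 8-fold, so its gene count carries no information. Alternatives covered normalization, background correction, the series table, the background filter, the label used for the day-7 groups, the variance prior, the probe of a gene, the arrays and blocks in each fit, the thresholds and the leaving out of each pair or treatment. Alternatives chosen after seeing the data were a run without the 3 arrays with disagreeing labels and the tests of list shifts by day.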

Results

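Liver expression was measured in 12 groups of 1 array each, vehicle, ATRA, DEN, ATRA+DEN, control siRNA and G0s2 siRNA at day 2 and at day 7. The median processed intensity of an array lay between 12.1 and 16.7. No group has replicates, so the errors given are those of effects averaged over pairs of arrays, and values of single arrays carry none. Positions are those of the array's probes on mouse genome build mm9.

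The siRNA arrays address what lowering G0s2, an inhibitor of the triglyceride lipase of fat cells and liver, does in the liver. G0s2 itself (chromosome 1, 195098925 to 195098984) was lower in the G0s2 siRNA array than in the control siRNA array by a log2 difference of -1.85 at day 2 and -1.19 at day 7, that is 3.60-fold and 2.29-fold. The lowest G0s2 level of the 12 arrays, 0.44, was in the ATRA+DEN array of day 2, against 4.28 in vehicle, 3.12 in ATRA and 3.33 in DEN at that day. At day 7 the levels were 3.93 in vehicle, 4.22 in the array titled ATRA, 3.39 in the array titled DEN and 2.83 in the array titled ATRA+DEN. The siRNA arrays held 3.84 (control) and 1.99 (G0s2) at day 2 and 3.45 and 2.26 at day 7.

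**Figure D1:**
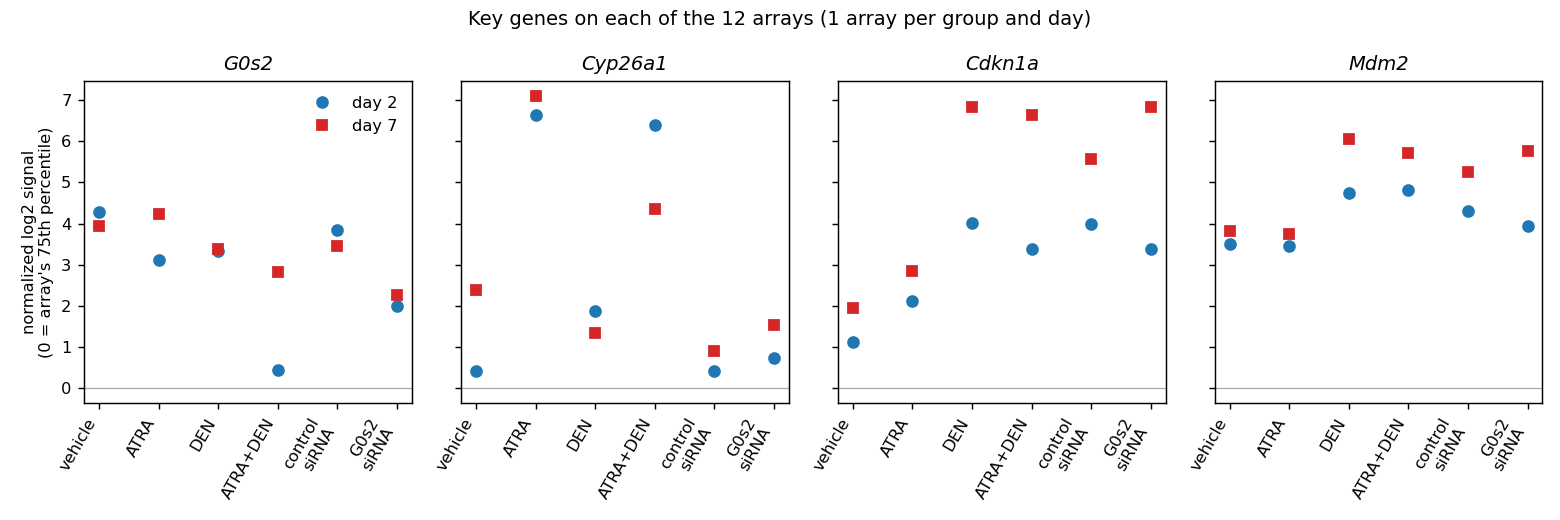
Normalized log2 signal (vertical axis, 0 is the array's 75th percentile) of G0s2, Cyp26a1, Cdkn1a and Mdm2 in each of the 12 arrays, by treatment, with day 2 as circles and day 7 as squares. Cyp26a1 is highest in arrays titled with ATRA, at 4.34 to 7.10, and Cdkn1a and Mdm2 are higher in DEN than in vehicle arrays on both days.

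DEN asks what a genotoxic carcinogen changes in the liver within days, with and without ATRA. Genes that p53, the transcription factor activated by DNA damage, switches on shifted up with DEN. The list median rose by 1.67 (log2) with 27 of 29 measured members higher, 21 of them in all 4 pairs, and 23 members passed when adjusted over the list alone. The list had an adjusted p = 9.96e-23 at the preset correlation and an adjusted p = 0.689 with an estimated correlation. Phlda3, an inhibitor of Akt signalling (chromosome 1, 137665642 to 137665701), was 59.4-fold higher (log2 5.89, SE 0.53, adjusted p = 0.135). Gdf15, a stress-induced cytokine, was higher by 3.48 (SE 0.40), Tnfrsf10b, a death receptor, by 3.30 (SE 0.45), and Cdkn1a, the cell cycle inhibitor p21, by 3.20 (SE 0.61). Psrc1, a spindle protein, was above background on none of the 4 arrays without DEN and was at least 4.36-fold higher with it. Cdkn1a was higher than vehicle by 2.90 at day 2 and 4.87 at day 7, and Mdm2, the ubiquitin ligase that restrains p53, by 1.23 and 2.22. None of these genes passed over all genes tested.

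Interferon response genes shifted up with DEN (median 0.38, 28 of 33 higher, adjusted p = 6.14e-07, and adjusted p = 0.762 with an estimated correlation). Their median was 0.67 without and 0.47 with ATRA at day 2, and 0.04 (17 of 33 higher) and 0.52 at day 7. Among them was Mx2, an antiviral GTPase, with 1.69 (SE 0.16, adjusted p = 0.135). The NRF2 and phase II list, genes of oxidant defence and conjugation, shifted up by 0.21 (15 of 22 higher, adjusted p = 0.00322, and adjusted p = 0.762 with an estimated correlation), with values of 1.30 for the glutathione transferase Gsta2 and 1.01 for the quinone reductase Nqo1. Red cell genes shifted down (median -0.38, 11 of 13 lower, adjusted p = 0.00105, and adjusted p = 0.689 with an estimated correlation). The globins Hbb-bt and Hba-a1 differed by -2.15 (SE 0.35) and -2.06 (SE 0.36), lower in all 4 pairs. Lipogenesis (-0.24, 21 of 26 lower), cholesterol synthesis (-0.29, 20 of 25 lower), ER stress (-0.23, 17 of 23 lower), circadian clock (-0.25, 17 of 22 lower), heat shock (-0.16, 16 of 19 lower), hepatocyte (-0.17, 25 of 26 lower) and sinusoidal endothelium genes (-0.25, 15 of 19 lower) also shifted down, with adjusted p from 0.000203 to 0.0332. With an estimated correlation the adjusted p of these 7 lists was from 0.689 to 0.790. For DEN against vehicle, the hepatocyte median lay at percentile 0.02 of random lists matched on level at day 2 and at 69.39 at day 7. Members with values were Thrsp, a lipogenic regulator (-1.29, SE 0.34), the fatty acid elongase Elovl6 (-1.14, SE 0.29), Mvd of the mevalonate pathway (-0.81, SE 0.27), the ER chaperones Creld2 (-1.41, SE 0.29) and Hyou1 (-1.13, SE 0.23), the small heat shock protein Hspb1 (-0.74, SE 0.24), the deubiquitinase Usp2 (-1.22, SE 0.26) and the urea cycle enzyme Cps1 (-0.63, SE 0.19). Outside the lists, the lipid transporter Mfsd2a (-2.43, SE 0.80) and the matrix protein Sparcl1 (-2.19, SE 0.54) were lower in all 4 pairs. Cplane1, a ciliary gene also outside them, was higher by 3.76 (SE 0.78), while another probe of it gave -0.01. The P450 Cyp2a4 (-2.19, SE 0.66), of the xenobiotic phase I and female-biased lists, which did not pass for DEN, was also lower in all 4 pairs.

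By limma, 0 genes passed for DEN in either direction. At an unadjusted p under 0.05 there were 1160 higher and 1438 lower, 2598 in total where 1059 were expected by chance. By 2-fold or more with the same sign in all 4 pairs, 178 genes were higher and 142 lower. The same count for ATRA was 114 and 102, so such genes alone do not show an effect of DEN. No list passed camera with an estimated correlation in any comparison. Of the lists that passed for DEN at the preset correlation, 1 also passed by fry, that of red cell genes (adjusted p = 0.0206). The p53 list did not pass by fry (adjusted p = 0.0806). In the other comparisons fry kept 1 passing list for the interaction, 3 for day and 0 for ATRA and G0s2 siRNA. The lists of DNA repair, PPARa targets, bile acid, apoptosis, acute phase, NKG2D ligands and MHC class I, neutrophil, stellate cell and matrix, cholangiocyte and progenitor, RNAi machinery, liver tumour and retinoid response genes passed in none of the 5 comparisons. Without the day-2 pair of ATRA+DEN and ATRA, the calls of lipogenesis (-0.18), cholesterol synthesis (-0.13), heat shock (-0.09) and circadian clock (-0.23) ended, without the day-7 pair of DEN and vehicle those of heat shock (-0.09) and sinusoidal endothelium (-0.15), and without the day-2 pair of DEN and vehicle that of sinusoidal endothelium (-0.24). The hepatocyte call was lost under quantile normalization, and with day-7 groups from the treatment characteristic the p53 call was lost, with a median of 0.50.

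**Figure D2:**
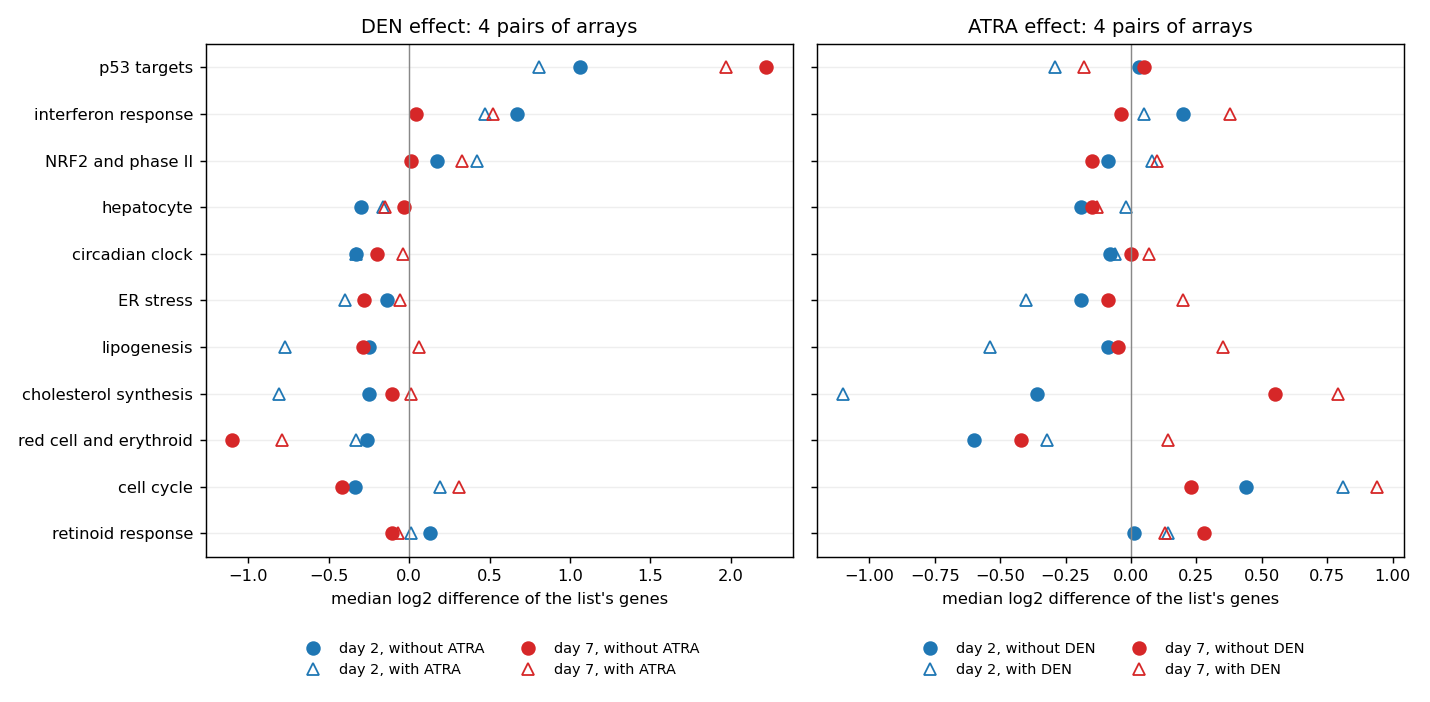
Median log2 difference (horizontal axis) of the genes of 11 lists in each of the 4 pairs of arrays that differ in DEN (left) and in ATRA (right), day 2 in blue and day 7 in red, filled circles without and open triangles with the other compound. The p53 list lies between 0.81 and 2.22 in the DEN pairs and between -0.29 and 0.05 in the ATRA pairs.

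ATRA asks what the retinoid changes in the same livers. Cyp26a1, the main enzyme that degrades retinoic acid (chromosome 19, 37775566 to 37775625), was 24.5-fold higher over 4 pairs (log2 4.61, SE 0.52, adjusted p = 0.618), with 6.21 and 4.53 at day 2 and 4.73 and 2.99 at day 7, without and with DEN. Cyp26b1, its paralog, was higher by 3.47 (SE 0.78), and Lrat, which esterifies retinol for storage, by 1.84 (SE 0.16). Raet1e, a ligand of the NKG2D receptor of natural killer cells, was higher by 3.71 (SE 0.68), and the metallothionein Mt2 by 2.01 (SE 0.34). Lower in all 4 pairs were Cyp8b1, the bile acid 12-alpha-hydroxylase (-1.26, SE 0.27), Cyp2a4 (-1.44, SE 0.32), the G protein subunit Gna14 (-1.51, SE 0.37), the prostaglandin synthase Ptgds (-1.46, SE 0.45) and Dcdc2a (-1.27, SE 0.45).

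Cell cycle genes shifted up with ATRA (median 0.60, 25 of 26 higher, adjusted p = 4.93e-12, and adjusted p = 0.689 with an estimated correlation), with 1.70 (SE 0.48) for the mitotic kinase Plk1, above background on 2 of the 4 arrays without ATRA, and 1.30 (SE 0.33) for the replication factor Mcm5. Hepatocyte genes shifted down by -0.15 (24 of 26 lower), red cell genes by -0.45 (9 of 13 lower) and markers of pancreas, muscle and fat by -0.53 (7 of 9 lower), with an adjusted p from 0.689 to 0.762 with an estimated correlation. Among random lists matched on level, the hepatocyte median lay at percentile 20.15 and 74.78 in the day-2 pairs without and with DEN. At day 7 it lay at percentile 2.6 and 4.9. The day-2 hepatocyte medians thus lay within the range of random lists of like level. The median of the pancreas, muscle and fat list was -1.76 and -0.13 in the day-2 pairs without and with DEN and 0.27 and -0.52 at day 7. In that list the vehicle array of day 2 stood apart, with DEN at -1.41 and ATRA+DEN at -2.07 against it. Without the pair that holds that array the median was -0.11 and the call ended, as did that of red cell genes (-0.28). The red cell call also ended without the day-2 pair of ATRA+DEN and DEN (-0.50) and without the day-7 pair of ATRA and vehicle (-0.41), and the pancreas call without the day-7 pair of ATRA+DEN and DEN (-0.36). In the pancreas list, the elastase Cela2a was above background on none of the 4 arrays with ATRA and on 2 of the 4 without. The retinoid response list had a median of 0.05 and a mean of 0.56 and did not pass (adjusted p = 0.0547), with 12 of its 20 measured members higher. By limma, 0 genes passed for ATRA. At an unadjusted p under 0.05 there were 736 higher and 494 lower, where 1059 in total were expected. At day 7 each ATRA pair spans 2 slides. With slide as a block the ATRA effect therefore rests on the 2 day-2 pairs of slide 1 alone. That fit gave 8 passing lists in place of 4, for day 2 only.

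The interaction of DEN and ATRA asks whether the DEN response differs when ATRA is present. Cell cycle genes had a higher DEN difference with ATRA than without (median 0.80, 25 of 26 members, adjusted p = 8.73e-11, and adjusted p = 0.689 with an estimated correlation). Their median DEN difference was -0.34 at day 2 and -0.42 at day 7 without ATRA, and 0.19 and 0.31 with it. T, B and NK cell genes (0.40, 11 of 15 higher, adjusted p = 0.0125, and adjusted p = 0.762 with an estimated correlation) shifted up, with 3.02 (SE 0.30) for Gzmb, a granzyme of cytotoxic cells, and 1.88 (SE 0.35) for the NK receptor Klrd1. Gzmb was above background on 4 of the 12 arrays and Klrd1 on 2, so both values rest largely on signal not above background. Their median DEN difference was -0.36 without and 0.27 with ATRA at day 2, and 0.02 and 0.03 at day 7. Inflammatory cytokines and chemokines (0.33, 15 of 18 higher, adjusted p = 0.00972, and adjusted p = 0.689 with an estimated correlation) also shifted up, with 1.84 (SE 0.24) for the neutrophil chemokine Cxcl1. Their median DEN difference was -0.22 and 0.19 at day 2 and 0.05 and 0.58 at day 7. Cholesterol synthesis genes shifted down (-0.26, 21 of 25 lower, adjusted p = 0.0158, and adjusted p = 0.823 with an estimated correlation). Their median DEN difference was -0.25 without and -0.81 with ATRA at day 2, and -0.11 and 0.01 at day 7. By limma, 0 genes passed, and 765 had an unadjusted p under 0.05, fewer than the 1059 expected by chance.

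For sets of genes chosen on the other day, the median DEN difference had the direction of the choice both with and without ATRA, though many single genes did not. At day 2, 861 genes higher with DEN at day 7 had a median of 0.22 without and 0.24 with ATRA, and 805 lower genes had -0.33 and -0.14. At day 7, 393 genes higher at day 2 had 0.45 and 0.36, and 344 lower genes had -0.32 and -0.28. Of the genes in these sets, 59.6 to 70.3% had that direction, against 45.5 to 54.5% of all genes. Without a background filter, the lower genes at day 7 gave 0.04 without and -0.46 with ATRA. The 2 DEN differences correlated across genes at r = 0.07 at day 2 and r = 0.32 at day 7, where genes are not independent replicates. These medians were not tested.

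With G0s2 siRNA, genes whose liver expression is higher in females were lower than with control siRNA and genes higher in males were higher. The female-biased list shifted down by -1.55 (14 of 16 lower, adjusted p = 1.40e-07) and the male-biased list shifted up by 0.68 (17 of 17 higher, adjusted p = 1.16e-07), each with an adjusted p = 0.689 with an estimated correlation. The female-biased median was -2.49 at day 2 and -0.39 at day 7, and its call ended without the day-2 pair, while the male-biased median was 1.02 and 0.36. At day 7 the control siRNA array stood apart in the female-biased list, with a median 1.12 above the ATRA+DEN array on its slide, where the G0s2 siRNA array differed by -0.07. The male-biased medians in the same differences were 0.27 and 0.59. Cyp2b13 differed by -4.69 (SE 0.98) and Cyp4a14 by -5.02 (SE 1.53), both P450 enzymes, but each was above background on 1 of the 2 G0s2 siRNA arrays, so the size of both is uncertain. The male-biased Cyp7b1 and Elovl3 differed by 1.57 (SE 0.30) and 1.69 (SE 0.69). Xenobiotic phase I genes shifted down by -0.49 (16 of 22 lower, adjusted p = 3.50e-06, and adjusted p = 0.689 with an estimated correlation), with Cyp2b9 at -3.71 (SE 0.43) and Cyp2b10 at -3.27 (SE 0.62).

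Kupffer cell and macrophage genes shifted down by -0.47 (17 of 21 lower, adjusted p = 1.12e-09, and adjusted p = 0.689 with an estimated correlation), and Marco, a scavenger receptor of macrophages, differed by -2.14 (SE 0.18, adjusted p = 0.346). The member that differed most, Ly6c1, a surface antigen of monocytes and endothelial cells, went the other way, at 3.98 (SE 1.04). Lipogenesis (-0.17, 19 of 26 lower), cholesterol synthesis (-0.15, 20 of 25 lower), interferon response (-0.25, 23 of 33 lower) and inflammatory cytokines and chemokines (-0.15, 14 of 18 lower) shifted down, and hepatocyte genes shifted up by 0.19 (22 of 26 higher), a direction that turned under quantile normalization (-0.03). The interferon median was -0.56 at day 2 and 0.12 at day 7. These 5 lists had an adjusted p from 0.762 to 0.823 with an estimated correlation. The hepatocyte median lay at percentile 72.47 of random lists matched on level at day 2 and at 38.4 at day 7. Lipid droplet and lipolysis genes, the list that holds G0s2, had a median of -0.01 and did not pass. The largest other differences among named genes above background on every siRNA array, with the same sign on both days, were as follows. Higher were Ly6a, a surface antigen of haematopoietic and endothelial cells (4.88, SE 1.25), Acot11 (3.36, SE 1.30), Dio1, the deiodinase that activates thyroid hormone (2.94, SE 1.77), and Rsph9 (2.85, SE 1.59). Lower were Sparcl1 (-3.81, SE 0.77) and Mfsd2a (-3.63, SE 1.13). Camk2b, outside that filter, stood at 3.33 and 3.29 with G0s2 siRNA and at -4.21 and -4.92 with control siRNA. It differed as widely between arrays without siRNA, at 2.87 and -3.07 in vehicle and -3.76 and 2.83 in DEN, at day 2 and day 7. Ly6a and Ly6c1 were also high without siRNA, at 6.42 and 7.51 in the array titled DEN of day 7. The differences of these 3 genes therefore cannot be assigned to the G0s2 siRNA. By limma, 0 genes passed for G0s2 siRNA, and 864 were higher and 574 lower at an unadjusted p under 0.05, where 1059 in total were expected. The spread was shared with the DEN pairs, and without the day-2 pair 3 lists passed in place of 9.

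Day 7 was compared with day 2 over all 6 treatments. By limma, 5565 genes were higher and 4353 lower at day 7, of which 1042 and 2507 carry predicted or clone names, and 629 and 1908 genes differed by 2-fold or more with the same sign in all 6 pairs. Dnm1, a dynamin, rose by 3.59 (SE 0.36, adjusted p = 0.000688), while its other probe gave 0.14, and the Wnt antagonist Dkk4 by 2.44 (SE 0.38) and Ciart, a repressor in the circadian clock, by 2.44 (SE 0.30), above background on 3 and 2 of the 6 day-2 arrays. H19, an imprinted non-coding RNA, Ffar4, a fatty acid receptor, and Wdr54 were above background on no day-2 array and were at least 3.17-fold, 2.02-fold and 1.61-fold higher at day 7. For H19 this holds for the probe used (2.49), while the lowest of its 4 probes gave 0.74. Other rises were in Pctp (2.81, SE 0.73), Syt10 (2.59, SE 0.31), Nrg1 (2.52, SE 0.59) and Inpp5e (2.46, SE 0.24, with another probe at -0.30). Pctp was above background on 1 and Nrg1 on 2 of the 6 day-2 arrays. The female-biased Cyp3a44 and Cyp2b13 changed by -4.42 (SE 0.50) and -3.04 (SE 0.69), and were above background on 2 and 1 of the 6 day-7 arrays. The oxidase Hao2, the NADPH oxidase Nox1, the ciliary gene Hydin, the odorant receptor Olfr122, the transporter Slc22a26 and the sperm channel gene Catsperg2 were above background on no day-7 array and were at least 6.66-fold, 5.19-fold, 4.51-fold, 3.44-fold, 2.62-fold and 2.44-fold lower there. Izumo1r (-3.50, SE 0.36) and Trio (-3.43, SE 0.18) also fell, while both other probes of Trio were higher, up to 0.43.

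Among lists, p53 targets shifted up from day 2 to day 7 (median 0.93, 25 of 29 higher, adjusted p = 0.0147), with 0.04 in the vehicle pair and 1.13 in the DEN pair. NRF2 and phase II genes (0.62, 19 of 22 higher), lipid droplet and lipolysis genes (0.63, 17 of 21 higher) and genes of gluconeogenesis and glycolysis (0.52, 19 of 24 higher) shifted up, with adjusted p from 0.00972 to 0.0158, and adjusted p = 0.689 with an estimated correlation, or 0.790 for p53 targets. Under quantile normalization the calls of these 3 lists ended, with medians of 0.37, 0.48 and 0.30, and that of p53 targets remained (0.79). Gstm1, a glutathione transferase, rose by 1.32 (SE 0.09), the lipid droplet protein Cideb by 1.01 (SE 0.10), Foxo1, a transcription factor of fasting metabolism, by 1.03 (SE 0.12) and Pck1, which commits carbon to glucose synthesis, by 1.21 (SE 0.32). The median of all genes moved by 0.109. No slide holds both days, so slide and day cannot be told apart, and slide as a random block left 2346 genes higher and 2375 lower. Without the 3 arrays whose labels disagree, 1288 were higher and 1955 lower.

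**Figure D3:**
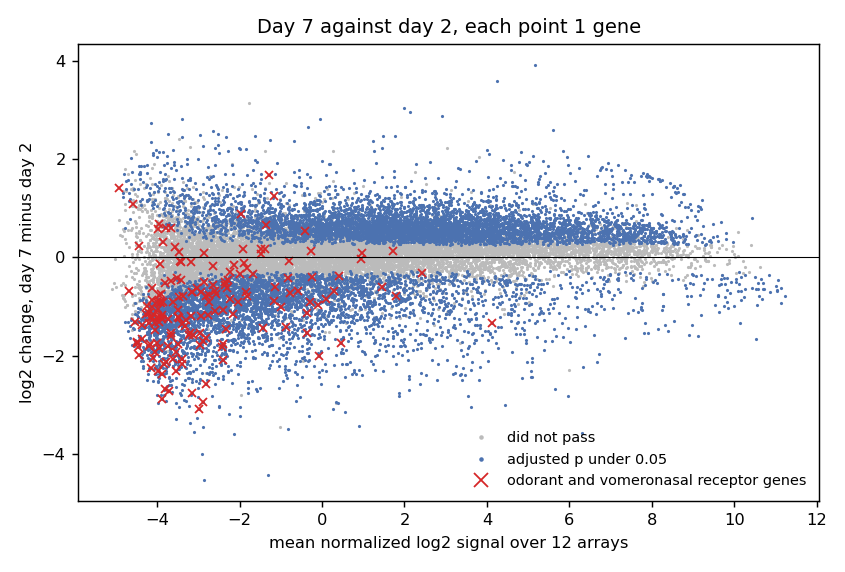
Log2 change from day 2 to day 7 (vertical axis) against the mean normalized log2 signal over 12 arrays (horizontal axis), 1 point per gene, with genes that passed in blue and odorant and vomeronasal receptor genes as red crosses. With genes ranked by level and divided into 4 equal bins, the median change was -0.42 in the dimmest bin and 0.32 in the brightest.

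Single arrays differed by 2-fold or more in 654 to 1772 genes. DEN against vehicle gave 408 genes higher and 424 lower at day 2, and 777 and 995 at day 7. ATRA against vehicle gave 456 and 419 at day 2, and 327 and 329 at day 7. ATRA+DEN against DEN gave 481 and 419 at day 2, and 740 and 639 at day 7, and against vehicle 631 and 513, and 614 and 690. G0s2 against control siRNA gave 340 and 314 at day 2, and 429 and 341 at day 7. In ATRA+DEN against DEN, all 25 measured cholesterol synthesis genes were lower at day 2 (median -1.10), with Sqle, the squalene epoxidase, at -3.39 (-0.30 for ATRA against vehicle), whereas 23 of 25 were higher at day 7 (median 0.79). The day-7 arrays with ATRA lie on slide 4 and those titled vehicle and DEN on slide 3, so slide and ATRA cannot be told apart there. At day 2, the immediate early gene Egr1 was higher with DEN by 3.04 without ATRA and 1.80 with it, and the histone chaperone Asf1b differed by -4.74 and -0.29. At day 7, Dio1 differed by -6.36 and -0.19 and Sult2a7, a sulfotransferase, by 4.76 and 2.77. These differences have no test.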

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

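Tests chosen only after the result was seen were the tests of list shifts by day and every test of an explanation below except the counts of other splits of the arrays.

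A difference between groups drew attention to 11 list shifts. The DEN effect on p53 targets was larger at day 7 than at day 2 by a median of 1.06 (27 of 29 members, adjusted p = 5.69e-15 over 66 tests). The DEN effect was also higher at day 7 for cholesterol synthesis (0.46), lipogenesis (0.42) and female-biased genes (0.70), and lower for interferon response genes (-0.27). The ATRA effect was higher at day 7 for cholesterol synthesis by 1.44 (24 of 25 members) and for lipogenesis by 0.42. Both day-7 ATRA pairs compare slide 4 with slide 3, whereas the day-2 pairs lie within slide 1. These 2 changes of the ATRA effect therefore cannot be told apart from a difference between slides. The DEN effect differed with ATRA for cell cycle genes (0.80), T, B and NK cell genes (0.40), inflammatory cytokines and chemokines (0.33) and cholesterol synthesis (-0.26). None of the 7 shifts by day passed with an estimated correlation, where the adjusted p was 0.958.

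The first pattern is the disagreement between labels on 3 day-7 arrays. If the treatment characteristic were right, the array titled DEN would come from a mouse given ATRA, yet its Cyp26a1 differed from vehicle by -1.03, where ATRA gave at least 4.53 at day 2. The array titled ATRA would hold DEN as well, yet its p53 target median lay 0.05 above vehicle, against 0.83 for ATRA+DEN at day 2. Both values argue against the characteristic. Cyp26a1 in the lower of the 2 arrays titled with ATRA exceeded the higher of the other 2 by 1.96, which the titles require.

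The second pattern is the large number of genes that differ between the days. Odorant and vomeronasal receptor genes, dim in liver, had a median change of -0.92, with 64.1% of 167 passing as lower and 3 as higher, which is consistent with dim probes reading higher on the day-2 slides. Dim probes are argued against as the only source, since 53.8% of the genes in the brightest of 4 equal bins of level passed. Of these bright genes 2348 were higher and 500 lower. The median change ran from -0.42 in the dimmest bin to 0.32 in the brightest. The share that passed therefore cannot decide whether a slide difference that varies with level also moved bright genes. With slide as a random block 4721 genes passed, but no slide holds both days, so slide and scan cannot be told apart from age, time on the compound or any other difference between days. Of 100 splits of the arrays, 1, the real one, gave as many genes as the 9918 of the days, and the highest other gave 2252. This argues against an arbitrary grouping of single arrays. It cannot exclude a chance difference between slides, because the days follow the slides and arrays on 1 slide were correlated (consensus 0.334).

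The third pattern is the level of p53 targets on the siRNA arrays, whose labels name no DEN, with a median above vehicle by 0.99 (control siRNA) and 0.85 (G0s2 siRNA) at day 2 and by 1.55 and 2.11 at day 7. At day 7 a difference between slides is argued against, since the control siRNA array lay 1.62 above the ATRA array on its own slide. At day 2 the siRNA arrays were alone on slide 2 and vehicle was on slide 1, so slide and siRNA cannot be told apart there. DEN in the drinking water of these mice may be the source, as the protocol places the siRNA on the day before DEN. It stays open, because 376 other genes higher in both day-2 DEN pairs had a median of 0.19 in the same difference (55.1% higher), between the bounds of 0.05 and 0.2 set for the test, where all genes had -0.06 (45.3% higher), and because the globins, lower with DEN, differed between the days. In the control siRNA array Hbb-bt and Hba-a1 stood at 3.37 and 4.10 at day 2, against 5.50 and 6.24 in vehicle, and at 5.71 and 6.78 at day 7, against 3.50 and 4.51.

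For DEN, chance cannot be excluded from the number of genes that passed with day as a block, since 4 of 34 splits of the 8 arrays gave as many genes as the real one, which gave 1, and the highest other gave 1. For ATRA the count says nothing about chance, because the real split gave 0 and all 34 splits reach that whatever they hold, and the highest other gave 1. The number of genes at an unadjusted p under 0.05 was counted only after those results were seen. It was 2255 for DEN, with 1892 in the highest other split, and 1102 for ATRA, with 2255 in the highest other split, which is that of DEN. Several splits that follow neither compound also exceeded the count of ATRA, among them those with 1892, 1626 and 1601 genes. The count therefore does not set ATRA apart from other splits.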

How the results depend on the processing

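Alternatives other than those leaving out 1 pair or treatment at a time kept direction and side of the threshold for 1440 values of named genes, ended 70 calls, gave 6 new calls and turned 27 directions. For medians of passing lists they kept 193, ended 86 and turned 5. The G0s2 difference between siRNA arrays stayed between -1.90 and -1.84 at day 2 and between -1.26 and -1.19 at day 7 under the 3 other ways of scaling. Signal over background limits the dim genes, since only 15752 of 21186 genes were above background on all 12 arrays. Where no cause is given below, the cause was not tested. The run without the 3 arrays whose labels disagree was chosen after seeing the data. The series table gave no value for day, because it was normalized within days.

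Normexp background with quantile normalization gave 5 genes up and 1 down for DEN and 1 up and 1 down for G0s2 siRNA, among them Phlda3 and Mx2 for DEN and Marco for G0s2 siRNA. A variance trend gave 3 up and 1 down for DEN and 1 down for G0s2 siRNA. Day in place of slide gave 1 gene for the interaction, and leaving out 1 siRNA pair gave 0 to 1 genes up for G0s2 siRNA. For ATRA, 0 genes passed under every alternative run. For day, slide as a random block gave 2346 up and 2375 down, the run without the 3 arrays 1288 and 1955, a 2-fold minimum 751 and 2117, and genes above background on all 12 arrays 2583 down, the last 2 by construction among fewer genes. Leaving out 1 treatment at a time gave 4338 to 5117 up and 3740 to 4098 down. Quantile normalization put 48.8% of the day calls upward, against 56.1%.

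The number of genes 2-fold apart between single arrays moved with the filter and the threshold by construction. In the order DEN, ATRA, ATRA+DEN against DEN, ATRA+DEN against vehicle and G0s2 siRNA, normexp gave 299, 302, 387, 447 and 233 at day 2 and 691, 210, 413, 439 and 219 at day 7. Genes above background on all 12 arrays gave 411, 418, 539, 614 and 343, then 1022, 342, 668, 705 and 420. No background filter gave 3418, 3486, 3322, 3929 and 3478, then 4935, 3817, 4551, 4674 and 3773. A 1.5-fold threshold gave 3002, 2915, 2897, 3425 and 2648, then 4513, 2397, 4067, 3762 and 2578, and a 4-fold threshold gave 173, 164, 133, 210 and 99, then 318, 100, 173, 225 and 114. Day-7 groups from the treatment characteristic gave 1772 for ATRA, 841 for ATRA+DEN against DEN and 656 for ATRA+DEN against vehicle.

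The number of passing lists was 0 in all 5 comparisons with an estimated correlation. For ATRA it was 2 under quantile normalization and with the authors' table, and 9 among genes above background on all 12 arrays. It was 4 to 11 when 1 pair was left out. With slide as a block it was 8, for an ATRA effect that then comes from the day-2 pairs alone. For the interaction it was 10 under normexp, 9 without a filter, 9 among genes above background on all 12 arrays, 8 by the characteristic and 7 with the mean of all probes. For day it was 1 under quantile normalization and 8 with the mean of all probes, and for G0s2 siRNA 3 to 12 when 1 pair was left out. The hepatocyte median for G0s2 siRNA turned to -0.03 under quantile normalization, -0.04 under normexp and -0.03 with the authors' table, and the interferon response median was -0.56 to 0.12 when 1 pair was left out. By the characteristic, cholesterol synthesis for DEN gave 0.01, and inflammatory cytokines for the interaction gave a median of 0.06 whose test had the opposite direction.

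The medians of the DEN response moved as follows. At day 2, genes up without ATRA gave 0.32 under normexp, 0.34 above background on all 12 arrays and 0.10 without a filter. At day 7, genes up gave 1.00 without and 0.66 with ATRA under normexp, 0.70 and 0.58 above background on all 12 arrays, and 0.24 and 0.08 without a filter. Genes down gave -0.53 and -0.18, then -0.62 and -0.17, then 0.04 and -0.46, and with ATRA -0.16 under quantile normalization and -0.15 with the authors' table. By the characteristic, day 2 gave -0.11 and -0.08 for genes up and -0.14 and 0.08 for genes down, and day 7 with ATRA gave -0.47 and 0.27.

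By the characteristic, these named genes turned. For DEN they were Cyp26a1 (2.23), Lrat (0.81), Hsd17b13 (0.72), Ccnb1 (0.43), Plk1 (0.04), Raet1e (2.02), Tek (-0.50) and Mrc1 (0.12). For ATRA they were Hsd17b13 (-0.95), H2-D1 (0.35) and Epb42 (0.03), and for the interaction Cyp26a1 (1.06), Cyp26b1 (0.49), G0s2 (0.10), Ccnd1 (-0.65), Raet1e (0.77) and H2-D1 (1.59). Without the 3 arrays, DEN gave Cyp26a1 0.61, Lrat 0.04, Ccnb1 0.01, Raet1e 1.08 and Tek 0, and ATRA gave Rsad2 -0.17, as did slide as a block. The mean of all probes gave Hsd17b13 0.79 for DEN and -0.01 for ATRA, and normexp gave Serpina1a -0.02 for G0s2 siRNA. Leaving out 1 pair gave -1.34 to 0.06 for Cyp26a1, -1.23 to 0.12 for Sqle and -1.80 to 0.22 for Raet1e under DEN, -1.06 to 0.22 for Cel under ATRA, and -1.98 to 0.80 for Sqle under G0s2 siRNA.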

Other observations

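The genes in this part were chosen after their values were seen, and no test was run on them. Both day-7 siRNA arrays differed from the ATRA+DEN array on their slide in cholesterol synthesis genes, with a median of -1.85 for control siRNA and -2.02 for G0s2 siRNA. Sqle stood at -0.02 and 0.78 in these arrays, at 5.15 in ATRA+DEN, the highest of the 12 arrays, and at 3.14 in vehicle of day 7. ATRA+DEN itself lay above that vehicle in these genes, by a median of 0.56. The metallothionein Mt1 stood at 8.83 and 8.05, where the other 10 arrays lay lower, with 5.20 in vehicle of day 7. Lpin1, a phosphatidate phosphatase and coactivator induced in fasting, stood at 4.00 and 4.26, against 1.71 in vehicle of day 7. Red cell genes had medians 1.22 and 0.98 above ATRA+DEN. At day 2, the acute phase gene Saa3 stood at 5.27 with control and 8.07 with G0s2 siRNA, against 1.41 in vehicle, and the interferon-induced chemokine Cxcl9 at 3.81 and 4.51, against 0.28.

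Several genes ranged widely between arrays. Ly6a ran from 0.44 in DEN of day 2 to 7.83 in G0s2 siRNA of day 7, and stood at 6.42 in the array titled DEN of day 7. Ly6c1 ran from 3.00 to 8.60 and stood at 7.51 in that array. The MHC class II gene H2-Eb1 ran from -2.22 in vehicle of day 2 to 4.19 in G0s2 siRNA of day 2. Camk2b switched between high and low values in arrays with and without siRNA, at 2.87 in vehicle of day 2 and -3.07 in vehicle of day 7, at -3.76 and 2.83 in DEN, at 3.33 and 3.29 with G0s2 siRNA and at -4.21 and -4.92 with control siRNA, and was above background on 7 of 12 arrays. Ctse, a cathepsin, ran from -5.84 to 1.93, also on 7 of 12. Dio1 ran from -0.63 in the array titled DEN of day 7 to 5.73 in vehicle of day 7.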
